A study of Mus musculus with 24 samples.

How the data were processed

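RNA from livers and hearts of Ppara WT and KO mice of both sexes was measured on 24 Affymetrix mouse genome arrays, with 3 pools of 4 animals in each of 8 groups. The authors processed the arrays with robust multi-array averaging (RMA), and the deposited values are log2 intensities. The version of the RMA software and the genome build were not given in the sources used here. The sorted values of the 12 arrays of a tissue nearly coincided and differed between the tissues, as in arrays normalized apart, with median intensities over all probe sets of 2.45 in liver and 3.03 in heart. Levels were therefore not compared across tissues, and only differences within a tissue entered the tissue-by-genotype test.

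The table held 45101 probe sets, of which 64 were controls. A probe table supplied with the data gave genes for 35877 probe sets, 34945 with a single gene and 932 with several, and gave none for 9160. Probe sets with several genes or none were not used for gene results. Each of the 18193 genes was represented by the single-gene probe set with the highest mean over all 24 arrays, 9010 genes had more than 1 such probe set, and 1417 were represented by a probe set whose name ends in _s_at or _x_at, which can bind related transcripts. No filter on dim genes was applied. Cyp4a10 and Cpt1b had no single-gene probe set and were not analysed here.

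Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on a cell-means model, two-sided tests, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The 12 liver arrays and the 12 heart arrays were fitted apart for the 4 comparisons of KO with WT, the 4 comparisons of females with males and the 2 sex-by-genotype contrasts, and all 24 arrays were fitted together for the tissue-by-genotype contrasts. The sex-by-genotype contrast is the KO effect in females minus that in males, and the tissue-by-genotype contrast is the KO effect in liver minus that in heart. In all, 12 comparisons were made. For 40 gene lists of pathways, cell types and sex-biased genes, fixed before the data were examined, the camera test of limma was run on lists with at least 5 measured genes, with a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists of a comparison. Members of each list were also adjusted over the list alone.

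Genes named in the text followed a rule set before the data were examined. In each comparison of KO with WT these were the 8 largest rises and the 8 largest falls among genes past the threshold whose 3 KO pools all lay above or all lay below the 3 WT pools. In the other comparisons these were the 5 largest positive and the 5 largest negative values past the threshold, apart from Xist and Y-linked genes. Up to 4 members of each described list and a fixed set (Ppara, Cyp7b1, Cyp4a14, Acot1, Ehhadh, Pdk4, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Cd36, Ucp3, Plin2, Gabpa and Dnmt3b) were added. Symbols that are only a clone or locus name were passed over.

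Labels were checked on Ppara, Xist and Y-linked transcripts. RNA quality was checked as the difference between 3 prime and 5 prime control probe sets, which lay between 1.11 and 1.66 for Actb in liver and between 0.451 and 0.63 in heart, and for Gapdh between 0.292 and 0.717 in liver and between 0.0834 and 0.193 in heart. Exact two-sided permutation tests of KO against WT gave p from 0.1 to 1, where 0.1, the value for Gapdh in female heart, is the smallest p that 3 pools against 3 allow.

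Alternatives tried were a fit of the compared arrays alone, a fit of all arrays (for tissue-by-genotype, of 1 sex), a trended and robust variance, array weights, renewed quantile normalization, centring on array medians, only genes with a mean level above the median, the mean of all probe sets of a gene, every probe set tested, exclusion of _s_at and _x_at probe sets, the estimated correlation, the pool number as a block, and each pool left out in turn. Leaving out heart pools 4 and 10 together was added after the data were seen. A pool left out leaves 2 in its group, and limma then pools the spread over the groups of the fit. The number of arrays limits the precision.

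The pipeline was tested on simulated data with log2 shifts of 0.5, 1 and 2 in known genes. Recovery at these sizes was 59.7%, 95.5% and 100% for KO against WT in female liver, 50.7%, 92.5% and 100% in male liver, 62.7%, 98.5% and 100% in female heart and the same in male heart. For the sex-by-genotype test it was 31.3%, 74.6% and 100% in liver and 31.3%, 83.6% and 98.5% in heart, and for tissue by genotype 35.8%, 88.1% and 98.5% in females and 32.8%, 94.0% and 100% in males. Some unshifted genes were called too, 22 of 174 called genes for tissue by genotype in males and 15 of 165 in females. For KO against WT it was 12 of 185 in female liver and 10 of 176 in male liver. In heart it was 9 of 195 in females and 15 of 201 in males. The lowest share was 5 of 183, for the sexes in WT liver. False calls for tissue by genotype may thus exceed the share that the threshold sets. A shifted gene list was found in all 12 simulated comparisons, with 0 of the 38 other lists called by the preset-correlation test of limma. Genes were simulated independently of each other, so the simulation does not test false list calls where list members are correlated.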

Results

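The series measured RNA in the livers and hearts of adult mice with and without PPARα, a nuclear receptor that binds fatty acids and raises the transcription of genes for their oxidation. The question was how far its loss changes each tissue in females and in males. Wild-type (WT) and Ppara knockout (KO) SV129 mice, 12 of each sex and genotype, were 10 to 12 weeks old and were sampled at zeitgeber time 14. Each array held RNA pooled from 4 animals, and each of the 8 groups of tissue, sex and genotype had 3 pools, which gave 24 arrays. Pools are named by their label numbers, with 1 to 3 for WT males, 4 to 6 for KO males, 7 to 9 for WT females and 10 to 12 for KO females in each tissue. Values are log2 intensities, and ± gives the SD over 3 pools. The median log2 intensity of single arrays lay between 2.43 and 2.49 in liver and between 3.01 and 3.07 in heart, and the number of arrays limits the precision. Genes passed at an adjusted p under 0.05 in limma over 18193 genes.

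Ppara itself, on chromosome 15, was lower in every KO pool than in every WT pool of its tissue and sex, yet its transcript was still detected. It fell from 8.47 ± 0.22 to 7.43 ± 0.16 in female liver and from 7.09 ± 0.16 to 5.56 ± 0.24 in female heart. In males it fell from 8.49 ± 0.18 to 7.37 ± 0.12 in liver and from 6.91 ± 0.17 to 5.65 ± 0.41 in heart. The position of its probes relative to the deleted part of the gene was not known. Xist, the RNA that coats the inactive X chromosome, followed the sex labels in all liver pools. In heart, male KO pool 4 had an Xist level of 6.62, against at most 3.12 in the other male hearts and at least 7.32 in female hearts. Eif2s3y, a Y-linked translation factor gene, reached 4.49 in that pool and 3.34 in female KO heart pool 10, where the other female hearts had at most 2.50. Transcripts of the skeletal muscle list also had a median of 4.99 in heart pool 4, against at most 3.44 in the other male hearts. These sex-linked genes were outside the rule for named genes except as a check of the labels.

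**Figure D1:**
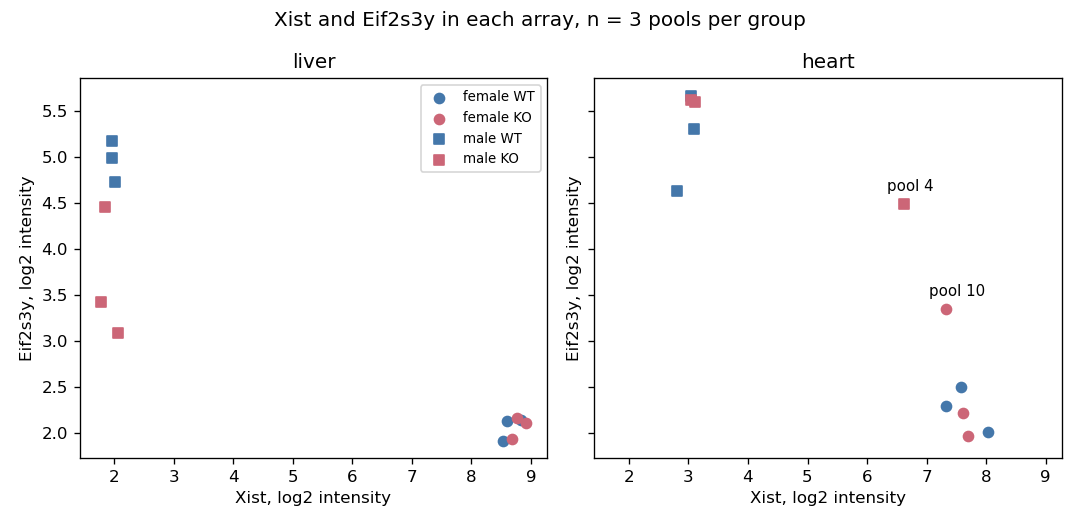
Log2 intensity of sex-linked transcripts in each pool, by tissue, sex and genotype, with 1 point per pool. Xist in heart male KO pool 4, at 6.62, lies between the other male hearts and the female hearts.

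Female KO livers held less RNA for fatty acid oxidation and more for cholesterol synthesis than female WT livers. Cyp4a14, a cytochrome P450 that hydroxylates fatty acids, fell 57.4-fold from 8.72 ± 0.79 to 2.88 ± 0.47 (n = 3 pools each, limma adjusted p = 0.000135). Vnn1, which releases the vitamin pantothenate from pantetheine, fell from 7.11 ± 0.21 to 2.34 ± 0.08 (limma adjusted p = 1.99e-10). The KO level of Vnn1 lay under the median of whole liver arrays, 2.45, so its fall is a lower bound, and that of Cyp4a14 lay near it, where a lower level can hardly be measured. Decr2, a peroxisomal dienoyl-CoA reductase, Retsat, which saturates retinol, and Slc25a20, the carrier of acylcarnitines into mitochondria, fell by 3.13, 3.07 and 2.09 on the log2 scale. Rad51b, a DNA repair gene, Adtrp and the lipid droplet coat gene Plin5 fell by 2.41, 2.30 and 2.04.

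The genes that rose most in female KO livers included Cyp7b1 and Slco1a1, which WT males expressed at higher levels than WT females. Cyp7b1, an oxysterol hydroxylase, rose 3.34-fold from 6.91 ± 0.51 to 8.65 ± 0.09 (n = 3 pools each, limma adjusted p = 0.000958). Slco1a1, an organic anion transporter, rose by 1.77 on the log2 scale. The sulfotransferase genes Sult5a1 and Sult1e1, the second of which inactivates estrogens, rose by 2.35 and 2.09. Unlike Cyp7b1 and Slco1a1, Sult1e1 was higher in WT females than in WT males. Meg3, an imprinted noncoding RNA, rose by 2.00, Dntt by 1.61, Hmgcs1, the cytosolic synthase at the start of cholesterol synthesis, by 1.58 and Limd2 by 1.55. Pdk4, a kinase that restrains pyruvate oxidation, rose from 2.49 ± 0.16 to 3.61 ± 0.28, and the fatty acid transporter gene Cd36 fell from 5.25 ± 0.44 to 3.74 ± 0.49. Acot1, Ehhadh, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Ucp3, Plin2, Gabpa and Dnmt3b did not pass. Their log2 differences ran from -0.63 for the peroxisomal enzyme gene Ehhadh (limma adjusted p = 0.0621) to 0.25 for Cyp8b1.

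Among pathways in female liver, 13 of 19 measured mitochondrial beta-oxidation genes fell, and 15 did when adjusted over the list alone, with a median log2 difference of -0.75. Besides Slc25a20 they included Eci2 at -2.03, Etfdh at -1.72 and Eci1 at -1.64. In the peroxisomal list 7 of 19 fell, and 11 did adjusted over the list alone (median -0.63), with Ech1 at -1.80, Acaa1b at -1.65 and the fatty acid importer gene Abcd2 at -1.37 beside Decr2. All 19 measured cholesterol synthesis genes had positive differences (median 0.88), 8 rose and 18 rose adjusted over the list alone, among them Msmo1 at 1.34, Cyp51 at 1.27 and Idi1 at 1.22. These 3 lists passed the camera test with the preset correlation and with an estimated one (adjusted p = 0.00148, 0.00148 and 0.0201). In the list of genes with male-biased liver expression 5 of 25 rose, 8 adjusted over the list alone (median 0.16), including Mup3 at 0.92 and C6 at 0.91 (adjusted p = 0.063 with an estimated correlation). In the interferon response list 2 of 31 rose, Psmb8 and Ifi27l2a, and 8 adjusted over the list alone (median 0.27, adjusted p = 0.0732 with an estimated correlation). Another 9 lists passed at the preset correlation and were lost with the estimated one (adjusted p from 0.063 to 0.56 with an estimated correlation), among them adipocyte markers (median 0.13).

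In all, 148 genes differed between KO and WT female livers, 66 higher and 82 lower, and 59 by at least 2-fold. Each had all 3 KO pools on 1 side of the WT pools, as had 10.4% of all genes, against 10% by chance. Array weights gave 326 genes, a fit of all 24 arrays 267, and a fit of the compared arrays alone 55, while 96, 90 and 88 passed without pools 7, 8 and 11. The balance of directions turned without pool 12, which stood apart from its sister pools, with 203 genes and 62.6% of them higher, and with array weights, with 57.4% higher, against 44.6% with all pools. Cd36 was not called without pool 8, 9, 10 or 11 or with the compared arrays alone (-1.74 to -0.94, adjusted p 0.000113 to 0.157 over its alternatives). Plin5 was not called without pool 7 or 8 or with the compared arrays alone (-2.43 to -1.55, adjusted p 5.31e-05 to 0.279), Slco1a1 with the compared arrays alone (1.49 to 2.03, adjusted p 2.03e-06 to 0.0935), and Limd2 without cross-hybridizing probe sets (0.55 to 1.75, adjusted p 5.8e-06 to 0.0596).

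**Figure D2:**
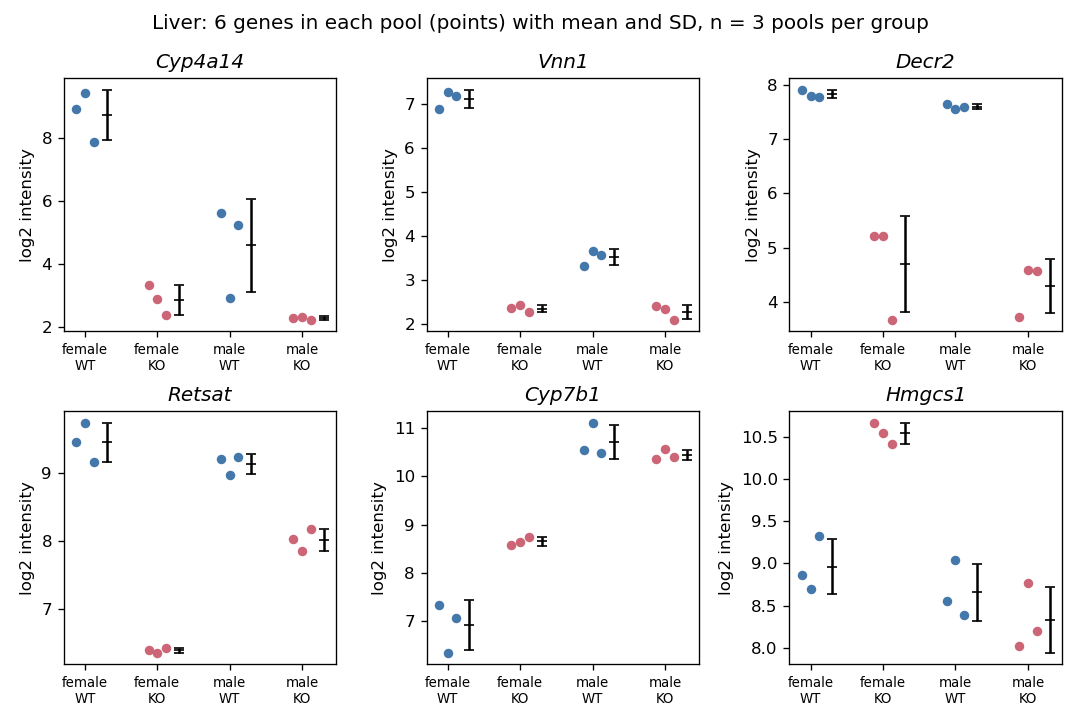
Log2 intensity of liver genes named in the text in each of the 12 liver pools, with 1 point per pool and bars for group means and SDs. Cyp4a14 falls in KO females to a mean of 2.88, and Cyp7b1 rises there to 8.65.

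Male KO livers also held less RNA for fatty acid oxidation than male WT livers. Decr2 fell 9.85-fold from 7.59 ± 0.05 to 4.29 ± 0.50 (n = 3 pools each, limma adjusted p = 0.000259), and Slc25a20 and the dienoyl-CoA isomerase gene Ech1 fell by 1.85 and 1.84 on the log2 scale. Mfsd2a, a transporter of lysophospholipids, fell by 2.42, Myom2, a sarcomere gene, by 2.46, Rtn4 by 2.15, Plin5 by 2.00 and Adtrp by 1.85. Asns, which makes asparagine, rose 5.06-fold from 3.47 ± 0.56 to 5.81 ± 0.98 (limma adjusted p = 0.0118). Meg3 rose by 2.05, Nat8 by 1.89, the nicotinamide methyltransferase gene Nnmt by 1.85, Dmbt1 by 1.57, the ectonucleotidase gene Nt5e by 1.47, the acetyl-CoA carboxylase gene Acacb by 1.24, Limd2 by 1.18 and Pdk4 by 0.90. Cyp7b1 stood at 10.44 ± 0.10 in KO and 10.71 ± 0.34 in WT males (limma adjusted p = 0.766), and Cyp4a14 at 2.29 ± 0.05 and 4.60 ± 1.47 (limma adjusted p = 0.143). Acot1, Ehhadh, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Cd36, Ucp3, Plin2, Gabpa and Dnmt3b did not pass, with log2 differences from -0.38 for Gabpa to 0.44 for Acot1. Eif2s3y, outside the rule and singled out after its values were seen, fell by 1.31 (limma adjusted p = 0.0373).

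In male liver 12 of 19 mitochondrial beta-oxidation genes fell, 14 adjusted over the list alone (median -0.49), with Eci2 at -1.83 and Etfdh at -1.60. In the peroxisomal list 5 of 19 fell, 8 adjusted over the list alone (median -0.28). Both lists passed with the preset and an estimated correlation (adjusted p = 0.00603 and 0.0158). None of 19 cholesterol synthesis genes passed over all genes and 1 was lower adjusted over the list alone (median -0.25, adjusted p = 0.626 with an estimated correlation). Another 4 lists were lost with the estimated correlation (adjusted p from 0.348 to 0.736 with an estimated correlation).

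The male comparison gave 110 genes, 31 higher and 79 lower, and 44 by at least 2-fold. Each had all KO pools on 1 side of the WT pools, as had 16.7% of all genes, against 10% by chance. A fit of the compared arrays alone gave 169 genes and a fit of all 24 arrays 180, and 60, 60, 69 and 55 passed without pools 1, 2, 3 and 5. Plin5 was not called without any 1 of the 6 pools (-2.34 to -1.91, adjusted p 1.02e-05 to 0.124 over its alternatives). Dmbt1 needed pools 1, 2, 3, 4 and 6 (1.21 to 1.86, adjusted p 0.000614 to 0.166), Pdk4 pools 1, 2, 3, 5 and 6 (0.76 to 1.07, adjusted p 0.00126 to 0.166), Asns pools 1, 3, 4 and 6 (2.03 to 2.90, adjusted p 3.6e-05 to 0.0817) and Nnmt pools 4 and 5 (1.44 to 2.10, adjusted p 4.82e-05 to 0.114). Asns, Dmbt1, Nnmt and Plin5 also missed the threshold with a trended, robust variance. Nt5e was not called with the mean of all its probe sets (0.57 to 1.69, adjusted p 2.02e-05 to 0.142), and Limd2 without cross-hybridizing probe sets or in a fit of all arrays (0.43 to 1.27, adjusted p 0.000258 to 0.303). Myom2 fell by 0.73 without cross-hybridizing probe sets.

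The effect of the KO on liver differed between the sexes in 12 genes, 9 more positive and 3 more negative in females. Vnn1 differed by -3.52 on the log2 scale (SE 0.17, limma adjusted p = 7.25e-07), Rad51b by -2.06 and Retsat by -1.94. In males Vnn1 stood at 3.51 ± 0.17 in WT and 2.27 ± 0.16 in KO, and Rad51b at 3.15 ± 0.27 and 2.80 ± 0.20, near the liver array median of 2.45, so a male fall as large as the female one could not have been measured. The cholesterol synthesis genes Hmgcs1, Msmo1 and Idi1 were more positive in females by 1.91, 1.61 and 1.58, Cyp7b1 by 2.01 (SE 0.30, limma adjusted p = 0.0367) and Myom2 by 2.24. Myom2 stood at 2.57 ± 0.21 in WT and 2.35 ± 0.27 in KO females, where a fall like that of males could not have been measured. All 19 measured cholesterol synthesis genes were more positive in females (median 1.06), 5 passed over all genes and 16 adjusted over the list alone, and the list passed with the preset and an estimated correlation (adjusted p = 0.0429). Another 7 lists were lost with the estimated correlation (adjusted p from 0.346 to 0.513 with an estimated correlation). Cyp4a14 and Cd36, called in females and not in males, did not pass this test of the difference, at -3.54 (limma adjusted p = 0.392) and -1.45 (limma adjusted p = 0.683). Ppara, Acot1, Ehhadh, Pdk4, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Ucp3, Plin2, Gabpa and Dnmt3b did not pass either.

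The count of 12 rested on single pools. It was 7, 4, 7, 4, 5, 5, 6 and 6 without pools 1, 2, 3, 4, 6, 7, 8 and 11, and 30 without pool 12. Of these genes 25% were more positive in females without pool 2 or 4, 42.9% without pool 3 and 40% without pool 6 or 7, against 75% with all pools, while array weights gave 26 genes, a fit of all arrays 31, renewed quantile normalization 7 and the mean of all probe sets 6. Vnn1, Rad51b and Retsat passed under each alternative tried. Cyp7b1 was lost without pool 1, 2, 3, 4, 5, 6, 10 or 11 (1.24 to 2.22, adjusted p 4.47e-05 to 0.156 over its alternatives), Hmgcs1 without pool 1, 2, 3, 4, 6, 7, 8, 10 or 11 (1.68 to 2.12, adjusted p 0.000117 to 0.158), Idi1 without pool 2, 3, 4, 5, 6, 7, 8, 10 or 11 (1.39 to 2.14, adjusted p 0.000147 to 0.161) and Msmo1 without pool 2, 3, 4, 6, 7, 8 or 11 (0.89 to 1.76, adjusted p 0.000633 to 0.109). Myom2 was lost without cross-hybridizing probe sets (0.63 to 2.41, adjusted p 6.37e-07 to 0.144). Cyp7b1 and Hmgcs1 were also lost with a trended, robust variance, Hmgcs1 and Idi1 after quantile normalization, and Cyp7b1, Idi1 and Msmo1 with the mean of their probe sets.

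Female and male WT livers differed in genes of the male-biased and female-biased lists and of beta-oxidation. Sult3a1 and Sult2a2, sulfotransferase genes, were higher in females by 9.39 and 8.35 on the log2 scale, from 2.13 ± 0.16 in males to 11.52 ± 0.11 in females for Sult3a1 (n = 3 pools each, limma adjusted p = 1.51e-14). Sult3a1 and Sult2a2 in males and Cyp4a12a and Hsd3b5 in females lay under the liver array median of 2.45, so their differences are lower bounds. Slc22a26, also under it in males, the hydroxyacid oxidase gene Hao2 and Cyp4a14 were higher in females by 4.87, 4.45 and 4.12, and Cd36 by 2.33. Cyp4a12a, which hydroxylates fatty acids, was lower in females at -8.19, from 10.33 ± 0.11 in males to 2.15 ± 0.32 in females, followed by Hsd3b5 at -6.21, Cyp2d9 at -4.82, the fatty acid elongase gene Elovl3 at -4.48, the complement gene C6 at -4.25 and Cyp7b1 at -3.80. Of the fixed lists, 17 of 25 male-biased genes were lower in females, 18 adjusted over the list alone (median -1.90), and 15 of 24 female-biased genes higher, 19 adjusted over the list alone (median 1.07). Both passed with an estimated correlation (adjusted p = 0.00051 and 0.000288). The mitochondrial beta-oxidation list was also higher in females (median 0.26, adjusted p = 0.0456 with an estimated correlation), with 2 of 19 genes called, Acadl and Hadha, and 12 adjusted over the list alone. In the peroxisomal list 5 of 19 genes, Acot3, Abcd2, Acot4, Ehhadh and Ech1, were higher and Scp2 was lower (9 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0237 with an estimated correlation). The hepatocyte marker list was also higher in females, with Ahsg called and 4 of 16 adjusted over the list alone (median 0.0709, adjusted p = 0.0456 with an estimated correlation), as was the X-inactivation list, with 2 of 6 called and 4 adjusted over the list alone (median 0.35, adjusted p = 0.0455 with an estimated correlation). Another 9 lists, steroid hormone and xenobiotic metabolism and stellate and fibroblast markers (median 0.15) among them, were lost with the estimated correlation (adjusted p from 0.0766 to 0.577 with an estimated correlation).

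In KO livers the sex difference ran the same way for the most extreme genes, with Sult3a1 at 9.69, Sult2a2 at 8.66, Slc22a26 at 5.26, Cyp3a44 at 4.31 and Sult1e1 at 3.70, and with Cyp4a12a at -7.80, Hsd3b5 at -6.02, Cyp2d9 at -4.65, Elovl3 at -4.06 and C6 at -3.72. Males lay under the array median for Sult3a1, Sult2a2, Slc22a26 and Cyp3a44 and females for Cyp4a12a and Hsd3b5, so these too are lower bounds. Cyp7b1 was lower in KO females by a smaller margin, at -1.79, and the interaction for this gene passed as described for the sex-by-genotype test. Cyp4a14 and Cd36 stood at 0.58 and 0.88 and did not pass. Cholesterol synthesis genes were higher in KO females than in KO males (median 0.92, adjusted p = 0.0465 with an estimated correlation), with 11 of 19 called and 14 adjusted over the list alone. The male-biased list had 16 of 25 genes lower, 18 adjusted over the list alone (median -1.47, adjusted p = 0.000566 with an estimated correlation). The female-biased list had 14 of 24 higher and 1 lower (18 and 2 adjusted over the list alone, median 0.99, adjusted p = 0.000476 with an estimated correlation). Another 13 lists were lost with the estimated correlation (adjusted p from 0.0655 to 0.327 with an estimated correlation), among them the hepatocyte list (median 0.0813).

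The sex difference covered 320 genes in WT livers, 146 higher in females and 174 lower, and 352 in KO livers, 210 higher and 142 lower. Of these, 94 were higher and 87 lower in females in both genotypes, against 1.69 and 1.36 by chance. Both genotypes share a spread estimate per gene, so these chance values, which treat the comparisons as independent, may be too low. Of the WT genes 45.6% were higher in females with all pools, and 50.9%, 53.4%, 52.5% and 50.2% without pools 1, 3, 8 and 9 and 51.8% after quantile normalization. Counts were 212, 212 and 206 in WT without pools 1, 2 and 3, and 219 and 223 in KO without pools 4 and 11. Of the KO genes 59.7% were higher in females with all pools, 47.7% without pool 10 and 72.4% without pool 12. Array weights gave 520 and 734 genes and a fit of all arrays 600 and 611 in WT and KO, and the compared arrays alone gave 190 in KO. Ehhadh, higher in WT females by 0.70, was not called without pool 1, 2, 7 or 8 (0.55 to 0.87, adjusted p 0.000814 to 0.0763 over its alternatives).

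Female KO hearts held less RNA for mitochondrial fatty acid oxidation than female WT hearts. Plin5 fell 8.24-fold from 7.44 ± 0.10 to 4.39 ± 0.14 (n = 3 pools each, limma adjusted p = 2.93e-10). Decr1, the mitochondrial dienoyl-CoA reductase gene, fell by 1.79 on the log2 scale, Slc25a20 by 1.76, Ech1 by 1.74, Ppara by 1.53, Plbd1 by 1.49, the muscle fructose bisphosphatase gene Fbp2 by 1.40, Cpt2, which re-forms acyl-CoA inside mitochondria, by 1.35 and the mitochondrial carrier gene Ucp3 by 0.64. Bdh1, which interconverts ketone bodies, rose 2.88-fold from 6.67 ± 0.19 to 8.20 ± 0.04 (limma adjusted p = 0.000816). Casq1, a calcium store protein of skeletal muscle, rose by 1.51, Btnl9 by 1.32, Bex1 by 1.19, Ndrg4 by 1.13, Fam81a by 1.03, Myot, a Z-disc gene, by 0.96 and the acyl-CoA synthetase gene Acsl6 by 0.84. Cyp7b1, Cyp4a14, Acot1, Ehhadh, Pdk4, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Cd36, Plin2, Gabpa and Dnmt3b did not pass, with log2 differences from -0.41 for Acot1 to 0.18 for Gabpa.

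In female heart 13 of 19 mitochondrial beta-oxidation genes fell, 16 adjusted over the list alone (median -0.64). In the peroxisomal list 4 of 19 fell, Ech1, Pex11a, Abcd3 and Hsd17b4, and 4 adjusted over the list alone (median -0.15). Both lists passed with the preset and an estimated correlation (adjusted p = 0.000352 and 0.00286). The Gapdh difference between 3 prime and 5 prime control probe sets was lower in all 3 KO than in all 3 WT female heart pools, with means of 0.104 and 0.172 (exact permutation p = 0.1, the smallest possible). In the atrial list the calcium pump regulator gene Sln, at -0.71, and the atrial myosin light chain gene Myl7, at -0.65, fell, and 4 of 9 did adjusted over the list alone (median -0.24, adjusted p = 0.191 with an estimated correlation). Lipogenesis genes had a median of -0.19, with 2 of 18 lower, Gpam and Me1, and 6 adjusted over the list alone (adjusted p = 0.0849 with an estimated correlation). Adipocyte markers had a median of -0.17, with Fabp4 higher, and 1 higher and 2 lower of 11 adjusted over the list alone (adjusted p = 0.702 with an estimated correlation). Red blood cell and cardiomyocyte markers, at -0.18 and 0.0514 with 0 genes called by limma, and the list of lipid droplets and lipolysis, at -0.17, were also lost (adjusted p = 0.593, 0.207 and 0.118 with an estimated correlation).

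In all, 97 genes differed in female heart, 22 higher and 75 lower, and 26 by at least 2-fold. Each had all KO pools on 1 side of the WT pools, as had 12.1% of all genes, against 10% by chance. The count was 61, 62 and 63 without pools 7, 8 and 10, and 59 without heart pools 4 and 10, an alternative added after the data were seen. Of these genes 22.7% were higher in KO with all pools, 18.0%, 19.4%, 11.1% and 14.3% without pools 7, 8, 10 and 12, and 10.2% without pools 4 and 10. Ucp3 was lost without pool 7, 8, 9, 10 or 11 (-0.78 to -0.47, adjusted p 0.00334 to 0.259 over its alternatives), Fam81a without the same pools (0.85 to 1.19, adjusted p 0.00134 to 0.168), Bex1 without pool 7, 8, 10 or 12 (0.88 to 1.42, adjusted p 0.00134 to 0.198) and Acsl6 without pool 7, 8, 10 or 12 (0.40 to 0.93, adjusted p 0.000936 to 0.272). These genes were also lost without pools 4 and 10 together, Ucp3 and Bex1 with the compared arrays alone, Ucp3 with arrays centred on their medians, Bex1 with a trended, robust variance and Acsl6 with the mean of its probe sets.

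**Figure D3:**
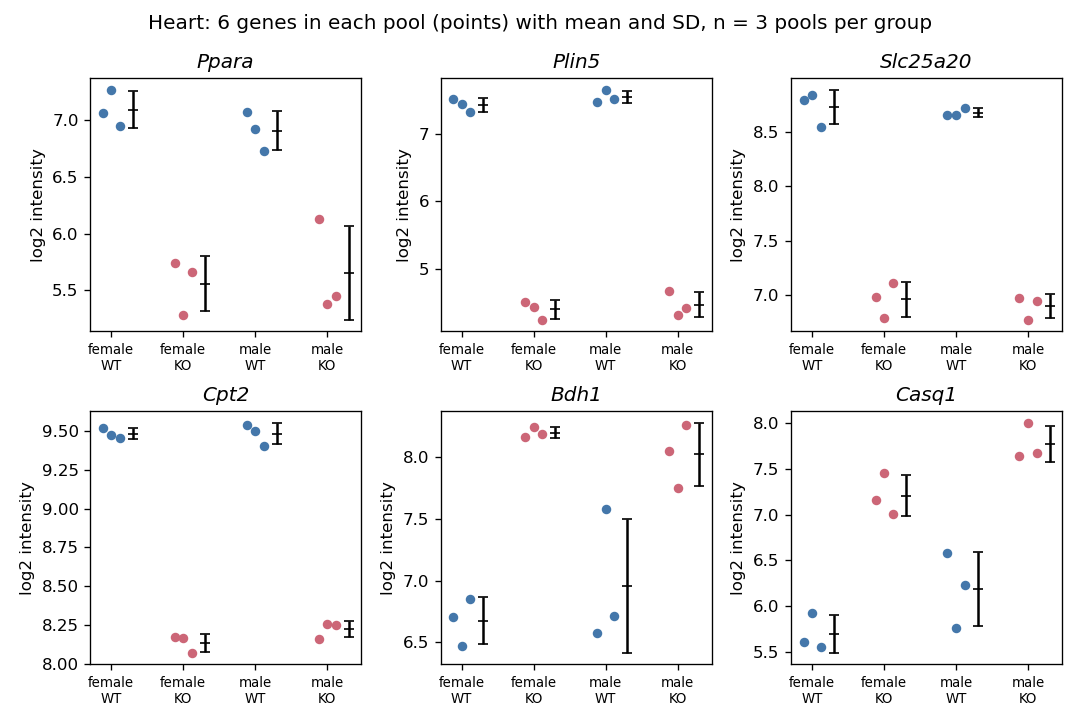
Log2 intensity of heart genes named in the text in each of the 12 heart pools, with 1 point per pool and bars for group means and SDs. Plin5 falls in KO hearts to means of 4.39 in females and 4.47 in males.

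Male KO hearts held less RNA for mitochondrial fatty acid oxidation than male WT hearts as well. The lipid droplet coat gene Plin5 fell 8.50-fold from 7.55 ± 0.09 to 4.47 ± 0.18 (n = 3 pools each, limma adjusted p = 2.36e-10), and Slc25a20 fell by 1.77 on the log2 scale, Decr1 fell by 1.67, Ech1 by 1.63, Plbd1 fell by 1.48, Fbp2 by 1.28, Cpt2 by 1.26, P3h4 by 1.25 and Ppara by 1.25. Casq1 rose 2.99-fold from 6.19 ± 0.41 to 7.77 ± 0.20 (limma adjusted p = 0.000179), Bdh1 by 1.07, the slow troponin gene Tnnt1 by 1.05, Ndrg4 by 1.04, Btnl9 by 0.97, Acsl6 by 0.90, the fast myosin light chain gene Myl1 by 0.78 and Ms4a6b by 0.77. Ucp3 stood at -0.49, Cd36 at -0.37 and Pdk4 at -0.22, and none of these passed, nor did Cyp7b1, Cyp4a14, Acot1, Ehhadh, Fgf21, Cpt1a, Cyp7a1, Cyp8b1, Plin2, Gabpa and Dnmt3b. In the mitochondrial beta-oxidation list 12 of 19 genes fell, 17 adjusted over the list alone (median -0.65). In the peroxisomal list 3 of 19 fell, Ech1, Abcd3 and Pex11a, and 6 adjusted over the list alone (median -0.10). In the list of fatty acid uptake and activation 2 of 19 fell, Acot2 and the fatty acid binding protein gene Fabp3, while 6 fell and 1 rose adjusted over the list alone (median -0.06). These lists passed with an estimated correlation (adjusted p = 0.000172, 0.0086 and 0.0322).

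The skeletal muscle list, with 0 of 12 genes called by limma and 1 higher and 1 lower adjusted over the list alone, had a median of 0.47 (adjusted p = 0.485 with an estimated correlation). Without pool 4, whose skeletal muscle and Xist levels stood apart, its median was 0.04 (adjusted p = 0.778, from 3.91e-06 to 0.778 over its alternatives). Lymphocyte markers had a median of 0.27 and stellate and fibroblast markers one of 0.12, with 0 genes called by limma in either, and these and the cell cycle list, at 0.15, were lost with the estimated correlation (adjusted p = 0.485, 0.485 and 0.569 with an estimated correlation). The male comparison gave 73 genes, 15 higher and 58 lower, and 23 by at least 2-fold, and 61 without pools 4 and 10. Of these genes 20.5% were higher in KO, against 30.9% without pool 5, 14.8% without pools 4 and 10 and 12.1% with the compared arrays alone. Each of the 73 had all KO pools on 1 side of the WT pools, as had 11.4% of all genes, against 10% by chance. Bdh1 was lost without pool 1, 3, 4 or 6 (0.88 to 1.38, adjusted p 0.000135 to 0.228 over its alternatives), Ms4a6b without the same pools (0.35 to 0.85, adjusted p 0.00416 to 0.395) and Myl1 without pool 3 (0.60 to 0.89, adjusted p 0.000569 to 0.085), and each with the compared arrays alone. Bdh1, Ms4a6b and Acsl6 were lost without pools 4 and 10 together, Bdh1 with a trended, robust variance, and Acsl6 (0.40 to 1.04, adjusted p 0.000324 to 0.328), Btnl9 (0.44 to 1.04, adjusted p 1.43e-05 to 0.152) and Ms4a6b with the mean of their probe sets.

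In heart no gene passed the test for a different KO effect in females and males, with 0 genes called by limma, 820 at an unadjusted p under 0.05 and a smallest adjusted p of 0.755. Of the genes named in every comparison, Ehhadh had the most extreme difference at -0.47, and Ppara stood at -0.28. The atrial list, with 0 of 9 genes called and 5 lower adjusted over the list alone, had a median difference of -0.49 (adjusted p = 0.478 with an estimated correlation). Another 5 lists were lost with the estimated correlation (adjusted p from 0.478 to 0.647 with an estimated correlation).

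The sexes differed in few heart genes. WT hearts gave 5 genes, Xist at 4.66 and Kdm6a, an X-linked histone demethylase gene, at 0.79 higher in females, and Eif2s3y at -2.94, Uty at -0.57 and the imprinted cell cycle inhibitor gene Cdkn1c at -0.57 lower. KO hearts gave Eif2s3y at -2.73 and Myl1 at -0.93, both lower in females. Xist did not pass there, at 7.55 ± 0.20 in KO females and 4.26 ± 2.04 in KO males, with male pool 4 at 6.62. The 4 heart groups share a spread estimate per gene, so pool 4 also widened that of Xist in the WT comparison. With pools 4 and 10 left out together the KO count was 5 and the WT count 6. The KO count was 4 without pool 4 or pool 10 and 0 without pool 5, 11 or 12. The WT count was 1 without pool 2 and 0 without pool 1, 3, 7, 8 or 9. The count of KO genes was also 0 with the compared arrays alone, 4 with the mean of all probe sets, 5 with a trended, robust variance and 11 in a fit of all arrays, which gave 13 in WT, where the mean of all probe sets gave 3. With every probe set tested, 3 passed in WT and 4 in KO hearts. Kdm6a (0.24 to 0.86, adjusted p 0.0146 to 0.775 over its alternatives) and Cdkn1c (-0.64 to -0.51, adjusted p 0.0246 to 0.356) were lost without any 1 of pools 1, 2, 3, 7, 8 and 9, and Myl1 without pool 5, 11 or 12 (-1.03 to -0.74, adjusted p 0.00084 to 0.571). Kdm6a was also lost with the mean of its probe sets and in a fit of all arrays, Cdkn1c after quantile normalization and without pools 4 and 10, and Cdkn1c and Myl1 with the compared arrays alone. Among the lists, X-inactivation genes were higher in WT females, with 2 of 6 called and 5 adjusted over the list alone (median 0.59, adjusted p = 0.0414 with an estimated correlation). Another 1 list in WT (adjusted p = 0.756 with an estimated correlation) and 6 lists in KO hearts (adjusted p from 0.0813 to 0.72 with an estimated correlation) were lost with the estimated correlation, the latter with atrial, skeletal muscle and cardiomyocyte markers at -0.39, -0.37 and 0.0712.

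Across the 4 KO comparisons, 19 genes were lower in both tissues and both sexes, and 0 genes were higher in all 4 by limma, out of 280 called at least once. The 19 were Ppara, Plin5, Slc25a20, Cpt2, Ech1, Decr1, Eci1, Eci2, Etfdh, Acadvl, Acads, Hadha, Hadhb, Abcd3, Retsat, Gna12, Hsdl2, Dhrs4 and Slc25a22, of which 12 belong to the beta-oxidation lists. Female and male livers shared 11 higher genes, among them Sult5a1, Meg3, Pdk4 and Apoa4, against 0.112 by chance, and 49 lower genes against 0.356. Female and male hearts shared 9 higher genes, among them Bdh1, Casq1, Myot and the cyclin gene Ccnd2, against 0.0181, and 49 lower genes against 0.239. Both sexes of a tissue share a spread estimate per gene, so these chance values, which treat the comparisons as independent, may be too low. Liver and heart shared 0 higher genes called by limma in females, against 0.0798 by chance, and 0 in males, against 0.0256. They shared 26 lower genes in females, against 0.338, and 21 in males, against 0.252. All chance values here also take every gene, dim ones included, as equally likely to be called.

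**Figure D4:**
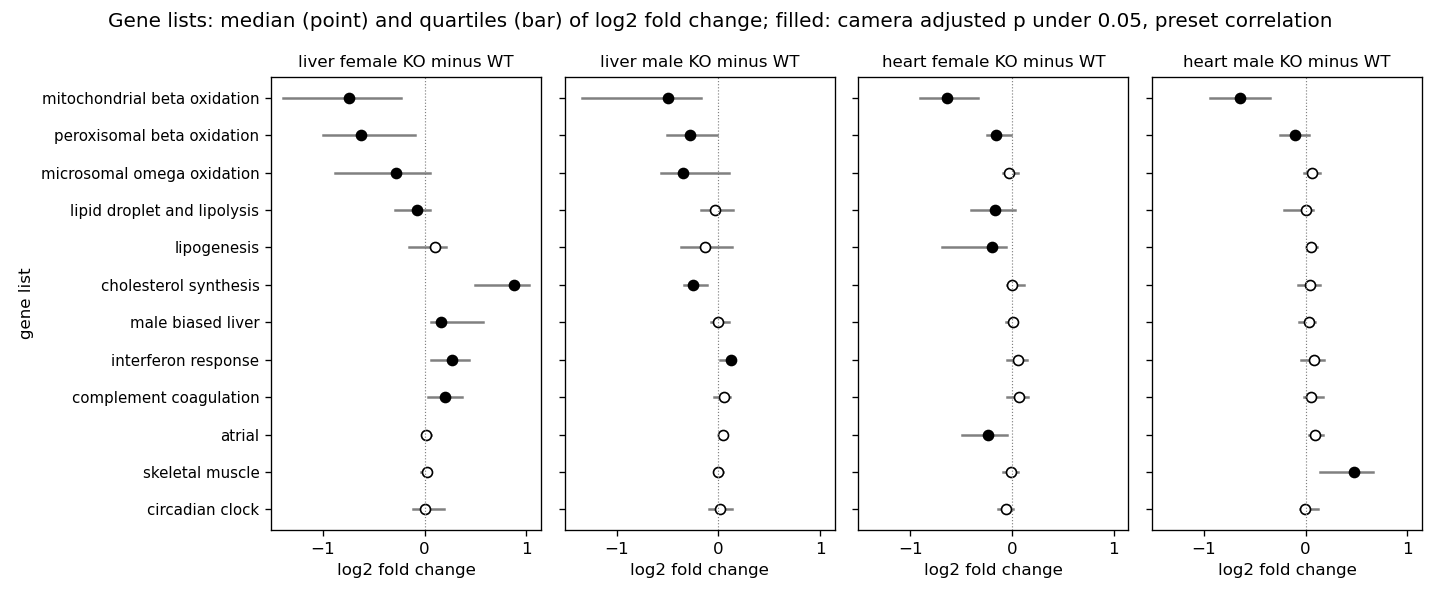
Median log2 difference, KO minus WT, of the measured members of fixed gene lists in each tissue and sex. The mitochondrial beta-oxidation list lies between -0.75 and -0.49 in all 4 comparisons, and the cholesterol synthesis list reaches 0.88 in female liver.

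The measured KO effect differed between the tissues in 127 genes in females, 68 more positive and 59 more negative in liver than in heart. Cyp4a14 differed by -5.82 on the log2 scale (SE 0.60, limma adjusted p = 2.45e-06), Vnn1 by -4.75, Decr2 by -3.12, Rad51b by -2.51 and Adtrp by -2.34. Sult5a1 differed by 2.53, Meg3 by 2.26, Sult1e1 by 2.08, Slco1a1 by 1.80, Cyp7b1 by 1.77 and Pdk4 by 1.18, and Cd36 by -1.42. For 25 of the 127, among them Cyp4a14, Vnn1, Decr2, Rad51b and Adtrp, a fall in heart as large as that in liver would have ended under the heart array median of 3.03, and for 12 a fall in liver as large as that in heart under the liver median of 2.45. Such falls could not have been measured, so for these genes the contrast does not show that the tissues respond differently. Both female heart groups lay under the heart median for 24 of the 127, Sult1e1, Cyp7b1, Mup3, C6, Cyp51, Idi1 and Sqle among them. Both female liver groups lay under the liver median for 11. For these genes the contrast sets a change in 1 tissue against signal near background in the other. The cholesterol synthesis list was more positive in liver, with 8 of 19 genes called and 15 adjusted over the list alone (median 0.91, adjusted p = 0.00911 with an estimated correlation). Its called members Cyp51, Idi1 and Sqle were near background in heart, so part of this difference sets liver against a heart signal not above background. The peroxisomal list was more negative in liver, with 4 of 19 called and 6 adjusted over the list alone (median -0.14, adjusted p = 0.00911 with an estimated correlation). The lipogenesis list, with Gpam called and 5 of 18 adjusted over the list alone, the steroid hormone list, with 2 of 20 called, and 2 higher and 1 lower adjusted over the list alone, and the male-biased list, with 4 of 25 called and 7 adjusted over the list alone, had medians of 0.36, 0.12 and 0.16 (each adjusted p = 0.0496 with an estimated correlation). Another 11 lists were lost with the estimated correlation (adjusted p from 0.0769 to 0.517 with an estimated correlation).

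In males the measured effect differed in 94 genes, 45 more positive and 49 more negative in liver. Asns differed by 2.12 (SE 0.43, limma adjusted p = 0.0155), Nat8 by 2.06, Nnmt by 1.97, Meg3 by 1.79, Acacb by 1.42 and Pdk4 by 1.12. Decr2 differed by -3.01, Mfsd2a by -2.43, Myom2 by -2.41, Rtn4 by -2.30 and Cnmd by -2.20. The same limit held for 18 of the 94 in heart, among them Decr2, Mfsd2a and Cnmd, and for 13 in liver. Both male heart groups lay under the heart median for 16 of the 94, Nat8 among them. Both male liver groups lay under the liver median for 10. The cholesterol synthesis list had 0 of 19 genes called by limma and 0 adjusted over the list alone (median -0.34, adjusted p = 0.527 with an estimated correlation), and the microsomal omega-oxidation list had Aldh3a2 called and 4 of 8 adjusted over the list alone (median -0.42, adjusted p = 0.35 with an estimated correlation). The first was also lost without pool 2, where its median was -0.16, and the second without pool 3 and among the more highly expressed genes (-0.45 to -0.25). In females 53.5% of the genes were more positive in liver with all pools and 48.1%, 46.9% and 43.8% without pools 7, 10 and 11 and 48.6% with the mean of all probe sets. In males it was 47.9%, and 50.9% without pool 5, 54.4% after quantile normalization and 53.3% with the mean of all probe sets. The female count was 79 without pool 7, 253 with array weights and 63 in a fit of the 12 arrays of that sex, and the male count was 58, 60 and 57 without pools 2, 3 and 5. Cd36 in females was lost without pool 8, 10 or 11, without heart pools 4 and 10, after quantile normalization, with a trended, robust variance and in the fit of 1 sex (-1.63 to -0.74, adjusted p 0.00491 to 0.169 over its alternatives). Pdk4 was lost without pool 7 or 10 in females (1.00 to 1.37, adjusted p 0.000147 to 0.0635) and, in males, without pool 1, 2 or 6 and with the pool number as a block (0.82 to 1.38, adjusted p 0.00241 to 0.125). Asns was lost without pool 1, 3, 4 or 6, without heart pools 4 and 10, with a trended, robust variance and in the fit of 1 sex (1.77 to 2.68, adjusted p 6.69e-05 to 0.15).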

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

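The tests on sex-linked transcripts of heart pools 4 and 10, on degraded RNA in liver pool 12, and on the hepatocyte share and the phase of the day behind the cholesterol synthesis genes were chosen only after the result was seen, as was leaving out heart pools 4 and 10.

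Heart male KO pool 4 carried Xist at 6.62, between the other male hearts (up to 3.12) and the female hearts (from 7.32), and female KO pool 10 carried Eif2s3y above the other female hearts. A second Xist probe set in pool 4 also exceeded the other male hearts, by 2.01 on the log2 scale, which is consistent with female heart material in that pool, while another, whose levels overlap between the sexes, had 2.69 in pool 4, within the other male hearts (2.47 to 2.92). A full exchange of the labels of pools 4 and 10 was argued against by Eif2s3y in pool 4, 1.99 above the female hearts other than pool 10. Female liver RNA was argued against by the hepatocyte list, whose median in pool 4 lay -0.12 from the highest other male heart. Alb stood at 3.14 in pool 4 and up to 5.02 in other male hearts. In female KO liver it stood at 13.6, on arrays that look normalized apart, so that value shows only that Alb is abundant there. Male material in pool 10 stays open, since Eif2s3y lay 0.85 above the other female hearts while Uty, a second Y-linked gene, did not exceed them in the probe set tested, which separated male from female hearts by only 0.24, and exceeded them by 0.07 in 1 of 3 other probe sets. Kdm5d, also Y-linked, did not exceed them in any probe set. In the Kdm5d probe set whose heart levels did not overlap between the sexes, pool 10 had 2.32, against at least 2.75 in male hearts. Pool 4 also stood apart in skeletal muscle transcripts, muscle or other female tissue was not tested as a source, and no biological explanation was tested.

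Liver female KO pool 12 had 106 genes more than 1 log2 unit from the mean of its 2 sister pools, 24 higher and 82 lower, against 40 for pool 10. RNA more degraded in pool 12 than in both sister pools was argued against by the Gapdh difference between 3 prime and 5 prime probe sets. It lay -0.42 from the higher of the sister pools. Pool 12 had the lowest Gapdh difference of the liver arrays, 0.292, and sister pool 10 the highest, 0.717. The Actb difference was 1.35 in pool 12 and 1.66 in pool 10. A difference in RNA quality with the sister pools more degraded was not tested and stays open. Renewed quantile normalization lowered the SD of the differences between pool 12 and the nearer sister pool from 0.27 to 0.26. For the other sister pool it went from 0.33 to 0.30. Both stayed above the other liver pairs, at most 0.23, which argues only against a level-dependent difference that this step removes. The sorted values of the liver arrays nearly coincided beforehand, so the step could change little. Another share of hepatocytes cannot be told apart, because the medians of the macrophage, lymphocyte, endothelial, stellate and cholangiocyte lists in pool 12 spread over 0.26, with macrophages at -0.20 and none of these 5 above by more than 0.1, although red blood cell markers, outside the test, lay at 0.18. The clock list of pool 12 lay -0.34 from its sister pools, and no biological explanation was tested, since the labels describe no animal apart.

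Cholesterol synthesis genes were higher in KO than WT female livers and not in males, with a median sex-by-genotype difference of 1.06. Pool 12 alone was argued against by the median without it, 1.16, and the medians without each pool lay between 0.91 and 1.16. Another hepatocyte share was argued against by the 8 hepatocyte genes with mean levels under 12, whose median difference was 0.013 (SD 0.316), and that level limit was set after the median of the whole list, -0.01, had been seen. The clock genes had a median absolute difference of 0.19 and a largest of 0.43, with 0 of 18 passing in limma adjusted over the list alone. These values argue only against another phase of the day that moves clock genes by more than this. The test recovered 31.3% of simulated log2 shifts of 0.5, adjusted over all genes, so a smaller phase difference cannot be told from none. A biological difference between females and males in how the KO acts on sterol synthesis stays open as a hypothesis, and was not tested apart from this comparison.

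The KO effect on liver differed between females and males in 12 genes. The named ones were Myom2 at 2.24, Cyp7b1 at 2.01, Hmgcs1 at 1.91, Msmo1 at 1.61, Idi1 at 1.58, Vnn1 at -3.52, Rad51b at -2.06 and Retsat at -1.94 (log2, females minus males), with Vnn1 and Rad51b in males and Myom2 in females too near background for a like fall to be measured. The lists were cholesterol synthesis at 1.06, mitochondrial beta-oxidation at -0.14, peroxisomal beta-oxidation at -0.12, lipogenesis at 0.19, male-biased liver genes at 0.24, interferon response at 0.14, antigen presentation at 0.18 and complement and coagulation at 0.20. Of these 8, all but cholesterol synthesis were lost with an estimated correlation (adjusted p from 0.346 to 0.513 with an estimated correlation). In heart the lists were lipogenesis at -0.17, lymphocyte at -0.28, cardiomyocyte at 0.0852, atrial at -0.49, skeletal muscle at -0.34 and oxidative phosphorylation at 0.054, and all 6 were lost with an estimated correlation (adjusted p from 0.478 to 0.647 with an estimated correlation).

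The measured KO effect differed between liver and heart in 127 genes in females and 94 in males. In females the named genes were Sult5a1 at 2.53, Meg3 at 2.26, Sult1e1 at 2.08, Slco1a1 at 1.80, Cyp7b1 at 1.77, Pdk4 at 1.18, Cyp4a14 at -5.82, Vnn1 at -4.75, Decr2 at -3.12, Rad51b at -2.51, Adtrp at -2.34 and Cd36 at -1.42. For 25 of the 127 a fall in heart like that in liver, and for 12 a fall in liver like that in heart, would have ended under the array median and could not have been measured. In males, with 18 and 13 such genes, they were Asns at 2.12, Nat8 at 2.06, Nnmt at 1.97, Meg3 at 1.79, Acacb at 1.42, Pdk4 at 1.12, Decr2 at -3.01, Mfsd2a at -2.43, Myom2 at -2.41, Rtn4 at -2.30 and Cnmd at -2.20. Both female heart groups lay under the heart array median for 24 of the 127, Sult1e1 and Cyp7b1 among them. Both male heart groups did so for 16 of the 94, Nat8 among them. Both liver groups lay under the liver array median for 11 genes in females and 10 in males.

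The lists that differed between the tissues in females and held with an estimated correlation were peroxisomal beta-oxidation at -0.14, lipogenesis at 0.36, cholesterol synthesis at 0.91, steroid hormone metabolism at 0.12 and male-biased liver genes at 0.16. Those lost with it were mitochondrial beta-oxidation at -0.15, microsomal omega-oxidation at -0.37, ketogenesis at -0.23, interferon response at 0.23, antigen presentation at 0.16, complement and coagulation at 0.12, endothelial at -0.17, cardiomyocyte at -0.15, atrial at 0.26, adipocyte at 0.37 and oxidative phosphorylation at -0.12 (adjusted p from 0.0769 to 0.517 with an estimated correlation). In males microsomal omega-oxidation at -0.42 and cholesterol synthesis at -0.34 were both lost with it (adjusted p = 0.35 and 0.527 with an estimated correlation). Of the cholesterol synthesis genes called in females, Cyp51, Idi1 and Sqle lay under the heart array median in both female heart groups.

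Probe sets without a listed gene, not used in the comparisons, also differed between KO and WT, 17 of 9160 in female liver, 5 in male liver, 14 in female heart and 12 in male heart.

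Regrouping the same arrays in other ways gave few genes in most comparisons. For each comparison of 3 pools with 3 there were 10 splits, too few for a share under 0.05, and 1, the real one, gave as many genes. The same held for tissue by genotype, where heart pools were moved with the liver pools of the same number. The labels do not say that a number marks the same mice, and moving the tissues apart, which allows more splits, was not done. The real count and the highest other were 148 and 1 for KO against WT in female liver, 110 and 1 in male liver, 97 and 0 in female heart and 73 and 1 in male heart. They were 320 and 0 for the sexes in WT liver, 352 and 0 in KO liver, 5 and 0 in WT heart, 2 and 0 in KO heart, 127 and 0 for tissue by genotype in females and 94 and 1 in males. Each of the other splits mixes the compared groups, so a difference between them enters its residual spread and may lower its count. For the sex-by-genotype test in liver, 1 of 100 splits drawn, the real one, gave as many as 12 genes and the next gave 7. Those splits mix KO with WT pools and so carry the KO effects in their residual spread, which may lower their counts, and chance is not called excluded from them. The split that exchanges the genotypes of all male livers was not among them and gave 248 genes, which points to a structure of the samples, because it adds the KO effects of both sexes. In heart the real split gave 0 genes by limma, with 820 at an unadjusted p under 0.05, so 100 of 100 splits necessarily gave as many and the count says nothing about chance. The split that exchanges the genotypes of all male hearts gave 161, which points to a structure of the same kind.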

How the results depend on the processing

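Leaving out heart pools 4 and 10 together was chosen after the data were seen, and the other alternatives before that. No named gene that passed changed direction under any of them. The camera direction of a list that passed was reversed for cell cycle without pool 6, with medians at -0.0435 for KO against WT in male heart (without other pools up to 0.24) and at 0.0367 for females against males in KO heart (down to -0.24). Medians also crossed 0, with an unchanged camera direction, for fatty acid uptake and activation (0.0472 without pool 9) and lipid droplets and lipolysis (0.00135 without pool 8) in female liver, and for skeletal muscle in the heart sex-by-genotype test (0.0324 without pool 4, 0.0195 without pools 4 and 10). The cause was not tested for any change. Of the named genes that passed, 15 of 19 kept their call in female liver, 11 of 18 in male liver, 13 of 17 in female heart and 12 of 17 in male heart under all alternatives. Signal near background limits falls of genes such as Cyp4a14, whose KO level in female liver was 2.88 against an array median of 2.45.

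With each pool left out in turn, KO against WT gave 88 to 203 genes in female liver (148 with all pools), 55 to 80 in male liver (110), 61 to 82 in female heart (97) and 63 to 81 in male heart (73). Sex by genotype gave 4 to 30 in liver (12) and 0 to 0 in heart, where limma called 0 genes and 820 had an unadjusted p under 0.05. Females against males gave 206 to 260 in WT liver (320), 219 to 421 in KO liver (352), 0 to 1 in WT heart (5) and 0 to 4 in KO heart (2). Tissue by genotype gave 79 to 135 in females (127) and 57 to 64 in males (94).

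A fit of the compared arrays alone, with fewer samples to estimate the spread, gave 55 genes in female liver, 169 in male liver, 190 for the sexes in KO liver and 0 in KO heart, and 63 for tissue by genotype in females. A fit of all arrays gave 267 in female liver, 180 in male liver, 31 for sex by genotype in liver, 600 and 611 for the sexes in WT and KO liver, and 13 and 11 in WT and KO heart. Array weights gave 326 in female liver, 26 for sex by genotype in liver, 520 and 734 for the sexes in WT and KO liver and 253 for tissue by genotype in females. The mean of all probe sets gave 6 for sex by genotype in liver, and 3 and 4 for the sexes in WT and KO heart, as did testing every probe set in heart. Quantile normalization gave 7 for sex by genotype in liver, with 57.1% more positive in females instead of 75%. A trended, robust variance gave 5 for the sexes in KO heart. Without heart pools 4 and 10 there were 59 in female heart and 5 for the sexes in KO heart.

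The labels number the pools alike in both tissues but do not say that a number marks the same mice, although the stated 12 mice per sex and genotype in 3 pools of 4 put the same animals in both tissues. Residuals of the same pool number in liver and heart correlated across genes with r from -0.196 to 0.105 (median 0.0294), over 0.1 in 1 of 12 pairs, and the own number was the best match in 4 of 12. With the pool number as a block, tissue by genotype gave 111 genes in females and 67 in males, and Pdk4 in males, at 1.12, was not called (adjusted p = 0.0731).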

Other observations

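The hypotheses of the pattern tests stand with the results they concern, and the genes below were chosen after their values were seen.

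In female and male KO hearts Slc22a5, the carnitine importer gene, fell by 1.04 and 0.89 on the log2 scale, the catalase gene Cat by 0.69 and 0.86, the malonyl-CoA decarboxylase gene Mlycd by 0.56 and 0.60 and the soluble epoxide hydrolase gene Ephx2 stood at -1.10 and -1.03. Gpam, which starts glycerolipid synthesis, fell by 0.93 and 0.94, and Me1, the cytosolic malic enzyme gene, by 0.87 and 0.84. Rbp7, a retinoid binding protein gene, rose by 0.60 and 0.63. In liver Slc22a5 fell by 1.76 in females and stood at -0.72 in males (limma adjusted p = 0.26), and Cat stood at 0.03 and -0.25 without passing.

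In KO livers of females and males Cyp26a1, which degrades retinoic acid, stood at -1.72 and -1.30, and the sterol exporter gene Abcg5 at -0.81 and -0.81. The apolipoprotein gene Apoa4 rose by 0.77 and 0.98, the anion transporter gene Slc22a7 by 1.42 and 1.09 and the phosphatidylcholine transfer protein gene Pctp by 0.81 and 1.04. Clock genes did not pass as a list in any of the 4 comparisons of KO with WT, with medians of 0.00 in female liver, 0.02 in male liver, -0.06 in female heart and 0.00 in male heart. Changes in opposite directions within the list would cancel in these medians and in the directional list test, so an unchanged clock does not follow. Macrophage markers had medians of 0.13, 0.04, -0.01 and 0.07 in the same order and did not pass, nor did the glucose use list, with medians of -0.04, -0.01, 0.04 and 0.05, although Pdk4 within it rose in both livers.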
